A study of Homo sapiens with 8 samples.

How the data were processed

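ATAC-seq libraries of 8 samples were analysed, 2 for each combination of cell line (KOSC-2, HSC-3) and dose (0 or 8 Gy, 24 hours before freezing). Groups and replicate numbers were taken from the labels. Each library had its own deposited peak list in the narrowPeak layout, without a header, so the lists were called per sample and no pooling is stated. The submitters' processing notes name FastQC 0.11.7, Bowtie2 2.3.4.2, SAMtools 1.9, deepTools, MACS2 2.2.6 and build hg19, without roles or parameters. The handling of duplicates and blacklisted regions and the shift of reads to the Tn5 cut site are not given in the sources used here. An absent shift would move summits by a few bases, which matters little for regions of this width.

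For each peak the authors deposited an integer score, which equals 10 times the −log10 q without its decimals, in every list. They also deposited a ratio, the fold enrichment at the summit over the background of the same library, and the −log10 p-value and −log10 q-value of the summit. The summit offset in bp completes each line. The lowest −log10 q over all lists was 2.02 and the narrowest peak 300 bp wide. Score, fold, p and q are the authors' values and are relative to one library, so they were used here only to describe, rank or filter peaks within a list. Peak heights were not compared between lists. The background and the enrichment of whole libraries, derived from these values as follows, were compared between libraries as measures of depth and quality, and local background in the closing part only relative to the median of its own library.

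Fold and p together fix the pileup at the summit and the background it was tested against, since the fold is (pileup + 1) / (background + 1) and p is the Poisson tail of the pileup. Pileups from 2 up to 400 were searched, and 100% of peaks in every list gave a whole number within 0.0001 of the deposited −log10 p. The lowest background of a list, which is its genome-wide level, was scaled from 300 bp fragments to reads per 10 kb and used as the measure of depth. Backgrounds above this level gave whole numbers of reads per 10 kb in 100% of cases. Depth by this measure was 64.8, 31.4, 41.0 and 24.3 reads per 10 kb in the KOSC-2 libraries (0 Gy replicates 1 and 2, then 8 Gy replicates 1 and 2) and 27.0, 20.2, 42.6 and 20.7 in the HSC-3 libraries. The smallest pileup called was 5 to 9 reads, so open regions with fewer reads were not detectable. Read totals are not used here, and no interval was computed from them.

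Peaks on chromosomes 1 to 22 and X were used. Peaks on all other sequences were left out. All lists were merged into a union of regions wherever peaks shared at least 1 bp, and a library was counted as calling a region where any of its peaks fell in it. The Jaccard index is the number of shared bases over the number of bases in either list. Line-only regions were called in 4 of 4 libraries of one line and 0 of 4 of the other. Gained regions were called in both 8 Gy libraries of a line and neither 0 Gy library, and lost regions the reverse. Runs are unbroken series of line-only regions among the regions called in 4 of 4 libraries of at least 1 line.

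Lines were compared by exact two-sided permutation tests of 4 against 4 libraries (70 assignments, smallest p 0.0286) and counts of regions by the 35 splits of the 8 libraries. Doses were compared with assignments exchanged within each line (36 assignments, smallest p 0.0556). Runs were compared with 1000 permutations of region classes within chromosomes, and the overlap of gained or lost regions between lines with two-sided Fisher's exact tests. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The regions named were fixed by rule before the data were examined, for the case that no gene annotation of the build was at hand: the 5 regions of each class with the highest mean percentile within their lists, and the 3 longest runs of each line. Chromosomes, and runs beyond these, were chosen after their values were seen.

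Alternatives set before the data were examined were a −log10 q of at least 5, lists cut to equal length by −log10 p (the shortest had 22504 peaks), at least 50% of a region covered, calls in at least 3 of 4 libraries, only peaks above the 50th percentile of their own list, overlap as the share of the shorter list's peaks, a replicate block, and each library left out in turn. The comparisons planned with gene lists, promoters and sequence motifs were not run, because they need gene positions or sequence of hg19, and the gene table at hand is of another assembly (GRCh38.p14). They are not analysed here.

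Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The functions were tested on simulated lists with planted classes and with randomly called regions, some of which met a class rule by chance and were counted with it. They returned 423 of 423 KOSC-2-only, 221 of 221 HSC-3-only, 392 of 392 gained and 289 of 289 lost regions, and the pileups of all 4793 simulated peaks. The same class rule was applied to the simulated calls and to the merged lists, and simulated regions did not touch. The check thus covers the merging of peaks and the recovery of pileups, and does not say how many calls of a class are noise.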

Results

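Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in KOSC-2 and HSC-3, established cell lines from oral squamous cell carcinoma. The labels call KOSC-2 radiosensitive and HSC-3 radioresistant. Cells of each line received 0 or 8 Gy and were frozen 24 hours later, with 2 libraries for each line and dose and 8 libraries in all. The stated purpose was to compare lines of different radiosensitivity across the genome, with and without irradiation. A single line stands for each class, so differences between the lines cannot be assigned to radiosensitivity. The labels do not say whether the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries. Each library came as its own list of accessible regions (peaks) on build hg19, and no gene annotation of that build was used here, so regions are given by position.

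The 4 KOSC-2 lists held 38321, 45526, 51764 and 42457 peaks, the first pair from unirradiated cells and the second from irradiated cells. The 4 HSC-3 lists, in the same order, held 42015, 23553, 22592 and 43176 peaks. Over chromosomes 1 to 22 and X, KOSC-2 lists averaged 44451 ± 5666 peaks (SD, n = 4) and HSC-3 lists 32752 ± 11282 (SD, n = 4), a difference of 11699 that the spread between libraries did not exclude (exact two-sided permutation test, p = 0.171). The median peak was wider in KOSC-2 (467 ± 7.87 bp) than in HSC-3 (431 ± 15.6 bp, SD, n = 4 each), without overlap between the lines (exact permutation p = 0.0286, the smallest that 4 against 4 allows, and 0.143 after Benjamini-Hochberg adjustment over 5 measures of the libraries). The total length covered was 25.02 ± 3.65 Mb in KOSC-2 and 16.7 ± 6.48 Mb in HSC-3 (SD, n = 4 each, exact permutation p = 0.0857, adjusted 0.214). Read totals are not part of the lists, so depth was read from the background under the peaks. It ranged from 20.2 to 64.8 reads per 10 kb over the 8 libraries. The median pileup at the summit of regions called in all 8 libraries was 21.9 to 67.3 times that background. This enrichment was lowest in the HSC-3 8 Gy library replicate 1 (21.9), the KOSC-2 0 Gy library replicate 1 (25.7) and the HSC-3 0 Gy library replicate 2 (34.7), against 49.6 to 67.3 in the other 5. The 2 short HSC-3 lists were thus also of low enrichment, one at each dose.

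**Figure D1:**
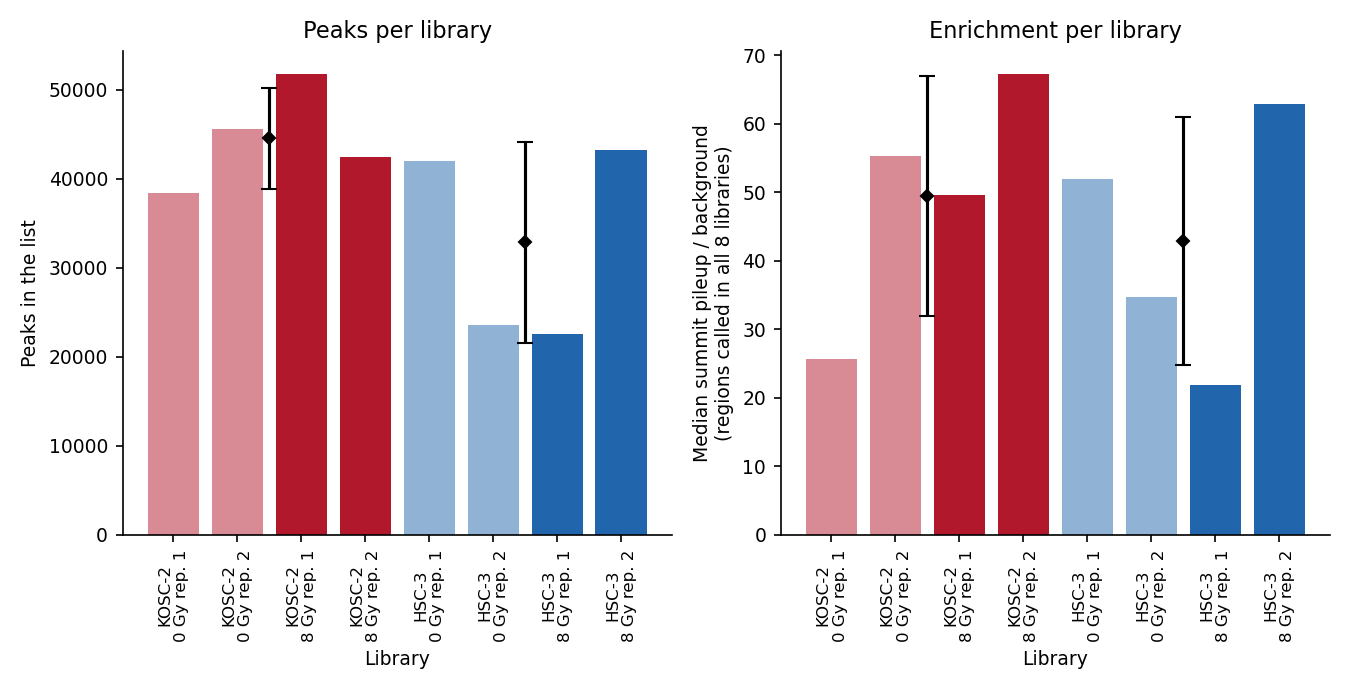
Peaks in each list (left) and the median summit pileup over background at regions called in all 8 libraries (right), for KOSC-2 (red) and HSC-3 (blue) at 0 Gy (pale) and 8 Gy (full colour); diamonds with bars are the mean and SD of the 4 libraries of a line. The lists hold 22592 to 51764 peaks and the enrichment runs from 21.9 to 67.3.

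The first comparison was between the lines. Merging all lists gave 80588 regions on chromosomes 1 to 22 and X, of which 12827 (15.9%) were called in all 8 libraries and 25728 (31.9%) in 1 library. Most of what was open in every library of a line was also found in the other line: 93.5% of the 25638 regions called in 4 of 4 KOSC-2 libraries were called in at least 1 HSC-3 library, and 98.3% of the 14572 regions called in 4 of 4 HSC-3 libraries in at least 1 KOSC-2 library. There remained 1671 regions open in all 4 KOSC-2 libraries and in 0 of 4 HSC-3 libraries (KOSC-2-only regions) and 242 regions with the reverse pattern (HSC-3-only regions). Together these 1913 line-only regions exceeded the count of every other split of the 8 libraries into 4 and 4, the highest of which was 861 (1 of 35 splits, exact p = 0.0286). No single region passes a test corrected over all regions, since its smallest exact p of 0.0286 becomes 1 after adjustment. Pairs of libraries of the same line shared more sequence (mean Jaccard index 0.495) than pairs from different lines (0.409), a difference of 0.0864 (exact one-sided test over 35 splits, p = 0.0286). Most of this came from KOSC-2, whose pairs averaged 0.561 (same dose) and 0.558 (different dose). HSC-3 pairs averaged 0.394 and 0.450, near the value of pairs from different lines. List length limits this index, and both same-dose HSC-3 pairs join a long list with a short one. They shared 87.6% of the shorter list's peaks, against 81.7% in same-dose KOSC-2 pairs and 76.6% between lines. Pairs of different dose shared 79.9% in HSC-3 and 80.0% in KOSC-2. The 2 long HSC-3 lists had an index of 0.573. With lists of equal length the difference by line was 0.0986 (exact one-sided test, p = 0.0286). Leaving out any 1 KOSC-2 library left differences by line of 0.0554 to 0.0902 and exact p of 0.0857 to 0.114.

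The balance between the lines depended on list length. With each list cut to its strongest 22504 peaks, 717 KOSC-2-only and 507 HSC-3-only regions were counted, a ratio of 1.41 in place of 6.90. Without the 3 libraries of lowest enrichment, an alternative chosen after seeing the data, the counts were 4526 and 3169, a ratio of 1.43. This left 3 KOSC-2 against 2 HSC-3 libraries, so the number of libraries that had to agree changed as well as the lists. Single libraries moved the counts as well. KOSC-2-only regions numbered 4254 without the KOSC-2 0 Gy library replicate 1 and 2650 without the HSC-3 0 Gy library replicate 1. HSC-3-only regions numbered 410 without the KOSC-2 0 Gy library replicate 1, 486 without the HSC-3 0 Gy library replicate 2 and 602 without the HSC-3 8 Gy library replicate 1. The total was 4664 without the KOSC-2 0 Gy library replicate 1 and 2925 without the HSC-3 0 Gy library replicate 1.

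The median distance to the nearest region called in all 8 libraries was 69.4 kb for KOSC-2-only regions (quartiles 23.1 and 260 kb) and 87.5 kb for HSC-3-only regions (34.3 and 249 kb), against 42.4 kb between regions called in all 8 (18.9 and 93.6 kb). The quartiles overlap widely and no test was run. Line-only regions were of middling strength, with a median percentile of 43.4 in KOSC-2 and 46.4 in HSC-3 within their own lists, against 76.1 for regions called in all 8. The strongest KOSC-2-only region was at chromosome 2, 78768363 to 78769462, with a mean percentile of 97.0 and an authors' fold enrichment of 14.8 to 16.7 over the 4 libraries. Next came chromosome 11, 100646788 to 100648259 (mean percentile 96.4), chromosome 12, 33948332 to 33949109 (95.9), chromosome 5, 16777873 to 16778843 (95.5), and chromosome 13, 63216987 to 63217596 (93.2). The strongest HSC-3-only region was at chromosome 14, 78669180 to 78670159, with a mean percentile of 99.3 and an authors' fold enrichment of 11.4 to 13.4. It was followed by chromosome 18, 7038225 to 7038964 (mean percentile 94.7), chromosome 13, 112686374 to 112687260 (93.6), and the chromosome 10 regions 37668859 to 37669455 (91.1) and 131791600 to 131792359 (90.5).

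**Figure D2:**
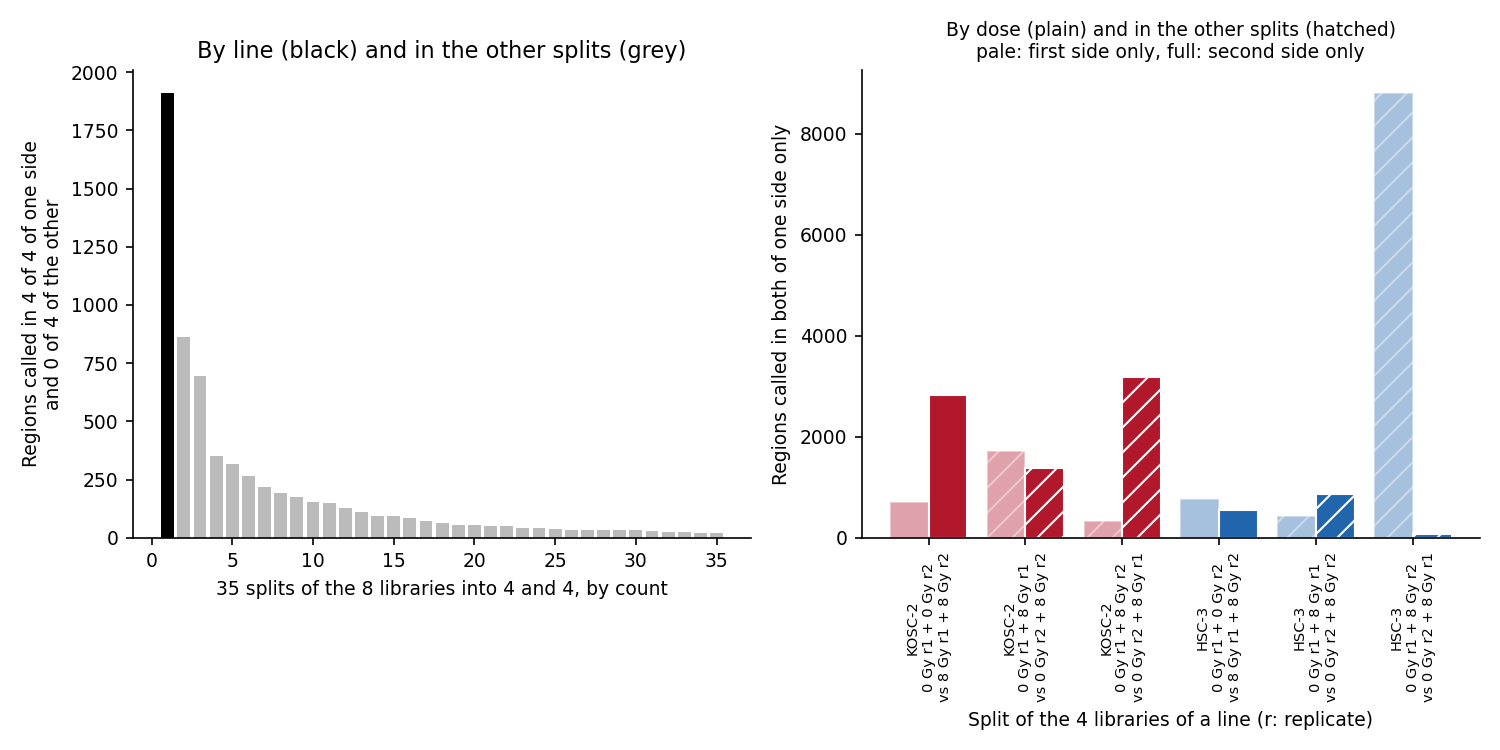
Left, the number of regions called in 4 of 4 libraries of one side and 0 of 4 of the other for the 35 splits of the 8 libraries, with the split by line in black (1913) and the highest other split at 861. Right, for the 3 splits of each line's 4 libraries into 2 and 2, the regions called only in the first side (pale) and only in the second (full colour), for KOSC-2 (red) and HSC-3 (blue); plain bars are the split by dose, with 701 and 2828 regions in KOSC-2 and 771 and 548 in HSC-3.

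The lines also differed in how their open regions were distributed over chromosomes. HSC-3 had a larger share of its peaks on chromosome 5 (6.84% ± 0.280 against 5.42% ± 0.365 in KOSC-2, SD, n = 4 each) and on chromosome 10 (5.68% ± 0.198 against 4.80% ± 0.0424). Its share was smaller on chromosome 16 (2.90% ± 0.236 against 3.60% ± 0.0699), chromosome 18 (1.44% ± 0.124 against 1.82% ± 0.113) and chromosome 19 (3.005% ± 0.337 against 3.53% ± 0.0883). In all, 13 of 23 chromosomes showed no overlap between the 4 values of each line, where chance gives 2.86% of chromosomes. HSC-3 was higher on chromosomes 4, 5, 8, 10, 14 and X and lower on 3, 7, 16, 18, 19, 21 and 22. Each of these 13 had the smallest exact two-sided permutation p that 4 against 4 allows (0.0286), which became 0.0505 after Benjamini-Hochberg adjustment over 23 chromosomes, so 0 passed at 0.05. No other split of the 8 libraries gave more than 1 chromosome without overlap.

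**Figure D3:**
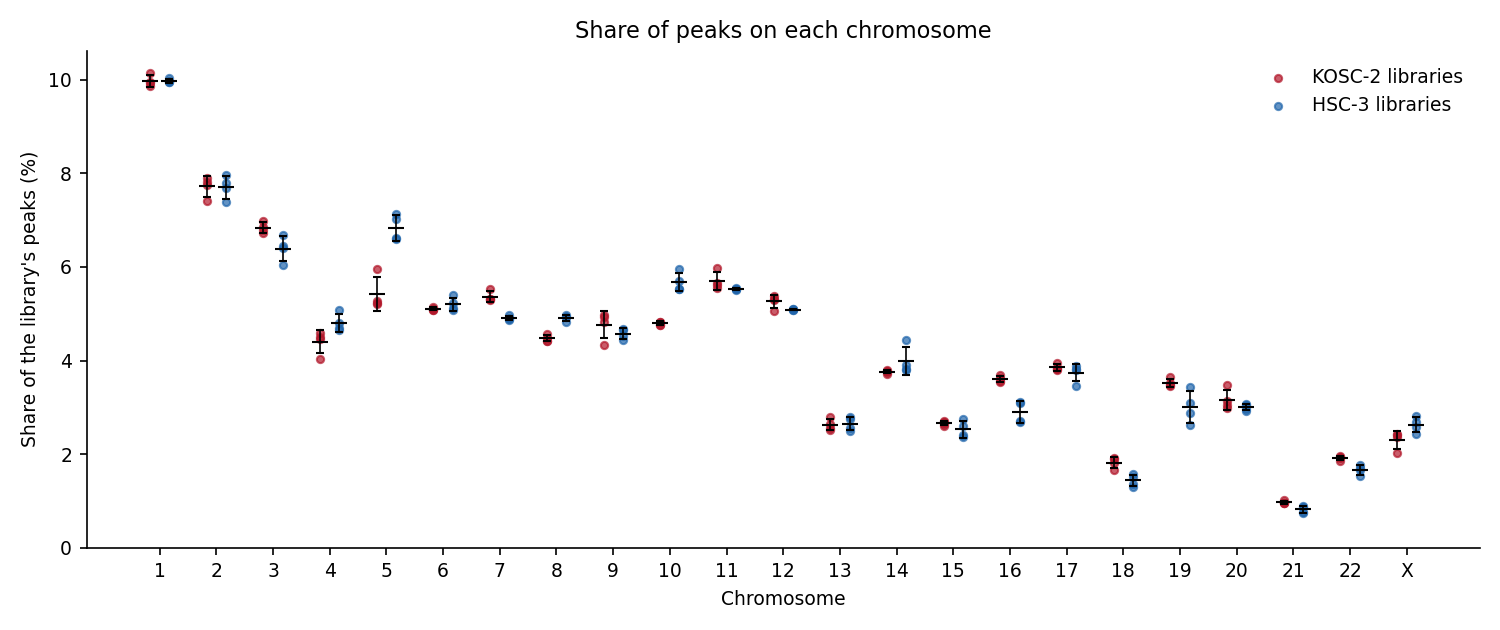
Share of each library's peaks on chromosomes 1 to 22 and X, in percent, for the 4 KOSC-2 libraries (red) and the 4 HSC-3 libraries (blue); black marks are means and SD. In percentage points the means differ most on chromosome 5, at 5.42% in KOSC-2 and 6.84% in HSC-3, and on chromosome 10, at 4.80% and 5.68%.

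KOSC-2-only regions stood in clusters. Among the 27383 regions called in all 4 libraries of at least 1 line, taken in order along each chromosome, the longest unbroken run of KOSC-2-only regions held 12, where 1000 permutations of the classes within chromosomes gave a median of 3 and a maximum of 7 (permutation p = 0.001, the smallest they can give). It spanned chromosome 11, 100238569 to 100920390, which held 39 regions of any kind with 95 calls in KOSC-2 libraries and 0 in HSC-3 libraries. The second, of 10 regions, spanned chromosome 4, 27102287 to 29710540, with 83 KOSC-2 calls and 0 HSC-3 calls in 32 regions. The third, of 8, spanned chromosome 11, 90077607 to 91980457, with 100 KOSC-2 calls and 0 HSC-3 calls in 43 regions. All 4 KOSC-2 libraries contributed at least 12 calls to each of these runs, most of them by definition, since every KOSC-2-only region is called in all 4. Runs of 5 or more numbered 18 and held 115 regions, 6.88% of the KOSC-2-only regions. They included 5 on chromosome 19, known for its clusters of zinc finger genes, and 4 on chromosome 13. HSC-3-only runs reached 3 regions (permuted maximum 3, permutation p = 0.035), at chromosome 2, 2743103 to 2767908, chromosome 4, 19740661 to 19852923, and chromosome 18, 6682787 to 7038964. The last held 12 regions with 34 HSC-3 calls and 0 KOSC-2 calls. Run lengths followed the lists used. With lists of equal length the longest KOSC-2-only run held 5 regions and lay elsewhere, at chromosome 6, 44224533 to 44458385, and the longest HSC-3-only run held 6, at chromosome 2, 2617107 to 2767908. Without the KOSC-2 0 Gy library replicate 1 they held 21 and 5, and without the HSC-3 0 Gy library replicate 2 they held 12 and 7.

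**Figure D4:**
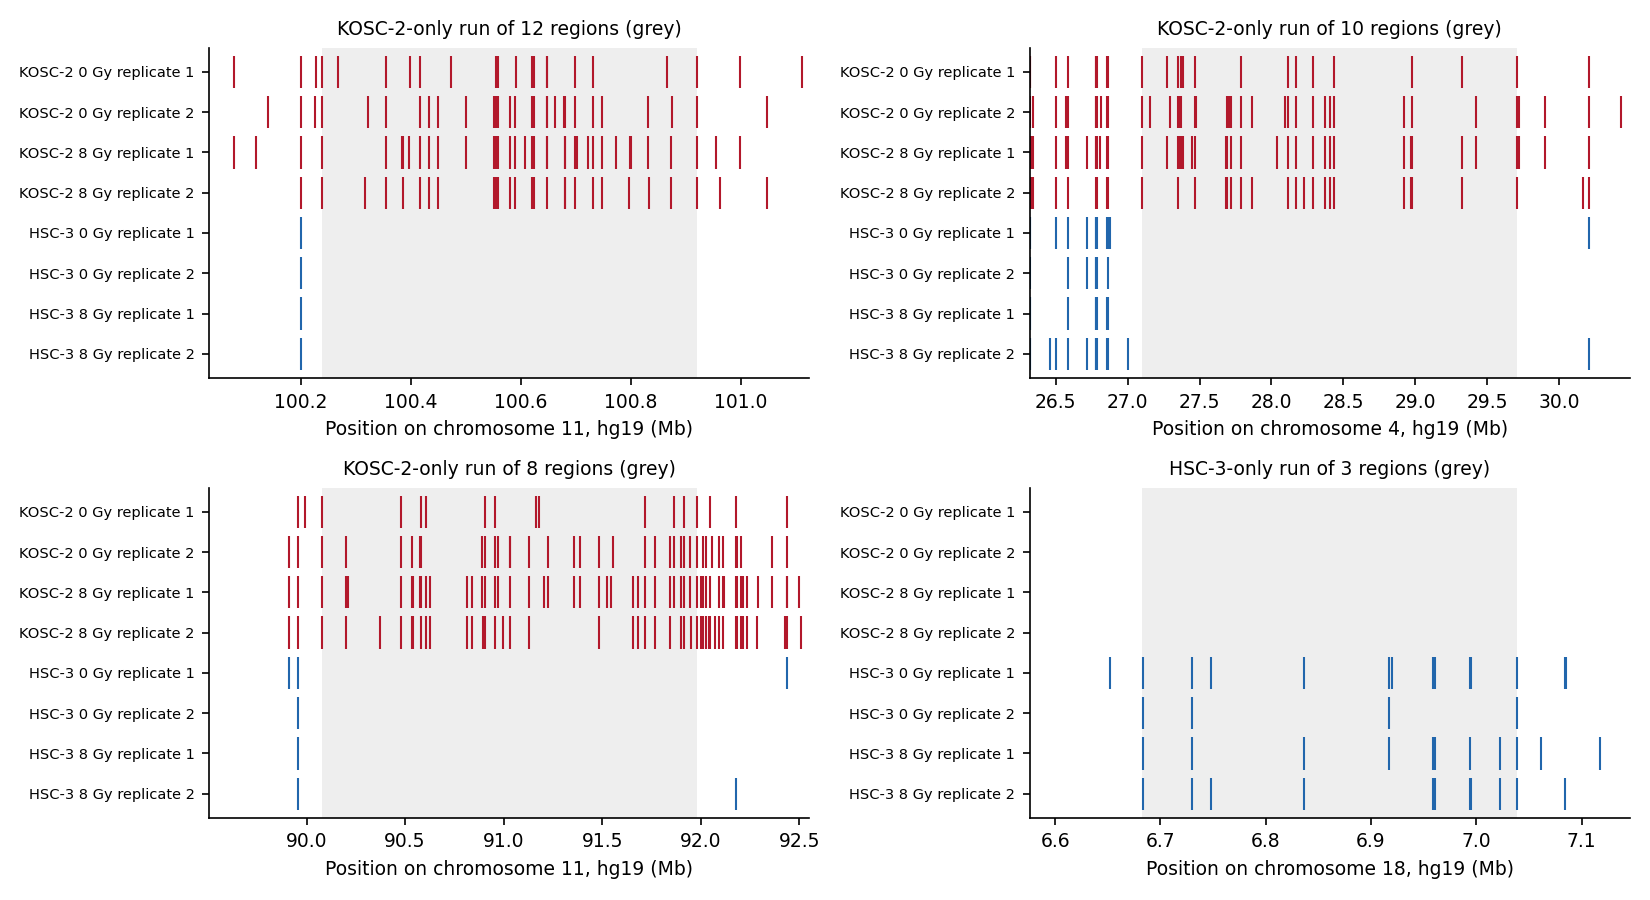
Peak calls of the 8 libraries (vertical marks, KOSC-2 red, HSC-3 blue) along the 3 longest KOSC-2-only runs, on chromosomes 11, 4 and 11, and the HSC-3-only run on chromosome 18, against position in Mb on hg19; grey marks the run. Inside the runs the other line has 0 calls.

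The second comparison was between 0 and 8 Gy. In KOSC-2, 2828 regions were called in both irradiated libraries and neither unirradiated one (gained), and 701 showed the reverse (lost). In HSC-3, 548 were gained and 771 lost. In KOSC-2 the split by dose separated 3529 regions, and the other 2 splits of its 4 libraries separated 3086 and 3514. In HSC-3 it separated 1319, and the others 1296 and 8892, the last being the split of the 2 long from the 2 short lists. With 3 splits per line no test can reach 0.05. Pairs of libraries of the same dose overlapped no more than pairs of different dose within a line (mean Jaccard index 0.477 and 0.504, exact one-sided test over 9 combinations, p = 0.444, smallest possible 0.111). The difference of -0.0268 turned to 0.0221 without the KOSC-2 0 Gy library replicate 2 and to 0.0472 with overlap as the share of the shorter list (exact p = 0.111). Both same-dose HSC-3 pairs join a long and a short list, which lowers their Jaccard index and raises that share. With lists of equal length the difference in Jaccard index was -0.00739 (exact one-sided test, p = 0.556). Peak numbers differed by 2643 between 8 and 0 Gy on average over the lines (exact two-sided permutation p = 0.667, smallest possible 0.0556), and by -1966 and -2503 without the HSC-3 library replicate 2 of 0 and of 8 Gy. None of the 23 chromosomes changed its share of peaks with dose at an unadjusted exact permutation p under 0.05, which this design cannot reach.

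The gained and lost regions were weak peaks. Their median percentile within the lists was 24.9 for KOSC-2 gained, 26.5 for KOSC-2 lost, 27.6 for HSC-3 gained and 29.2 for HSC-3 lost regions. The strongest gained region in KOSC-2 was at chromosome 10, 5590571 to 5591247, with a mean percentile of 78.1. The others named by the rule were on chromosome 12, 89319590 to 89320423 (74.8), chromosome 17, 9739265 to 9739749 (68.2), chromosome 3, 100712139 to 100712538 (67.7), and chromosome 5, 126590518 to 126591012 (67.1). In HSC-3 the strongest gained region was at chromosome 4, 165125458 to 165126044 (mean percentile 76.0), followed by chromosome 16, 71372024 to 71372507 (72.9), chromosome 20, 58405909 to 58406553 (63.1), chromosome 5, 96216059 to 96216453 (62.9), and chromosome 19, 4145442 to 4146190 (60.8). Lost regions in KOSC-2 were led by chromosome 9, 114714843 to 114715293 (mean percentile 66.6), chromosome 11, 109490227 to 109490668 (66.2), chromosome 5, 21808011 to 21808534 (65.9), chromosome 12, 27500652 to 27501116 (64.3), and chromosome 5, 67611471 to 67612036 (63.4). Those in HSC-3 were led by chromosome 10, 82258462 to 82258933 (mean percentile 79.2), chromosome 12, 123371502 to 123372356 (75.8), chromosome 10, 87403584 to 87403996 (70.8), chromosome 15, 57998477 to 57999402 (70.3), and chromosome 8, 37898896 to 37899341 (69.4).

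Single libraries decided the balance of gained and lost regions. The KOSC-2 ratio of gained to lost was 4.03 with all libraries, 1.25 with all lists cut to one length, and 0.738, 1.44, 2.31 and 9.96 without the 0 Gy replicates 1 and 2 and the 8 Gy replicates 1 and 2, in that order. In HSC-3 it was 0.711 with all libraries and 1.84, 0.0893, 9.75 and 0.472 in the same order. Leaving out a library makes the rule easier to meet for its dose, so these ratios move partly by construction.

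The third comparison asked whether the lines shared regions that changed with irradiation. Of the 1602 regions called in exactly 2 libraries of each line, 31 were gained in both lines, against 21.7 for independent lists (odds ratio 1.73, two-sided Fisher's exact p = 0.0214, 0.0854 after Benjamini-Hochberg adjustment over 4 overlaps). Regions lost in both numbered 11, against 8.40 (odds ratio 1.38, Fisher's exact p = 0.350, adjusted 0.350). In the 32 pairs of splits that mix doses in at least 1 line, the odds ratio ran from 0 to 3.31 with a median of 0.993. Regions are not independent replicates, so these p-values describe these lists. Gained regions shared by the lines numbered 360 without the HSC-3 8 Gy library replicate 1, 102 without the HSC-3 0 Gy library replicate 1, 87 without the KOSC-2 0 Gy library replicate 2, 76 without the KOSC-2 8 Gy library replicate 2 and 56 without the HSC-3 8 Gy library replicate 2. Lost regions shared by the lines ranged from 14 without the HSC-3 8 Gy library replicate 1 to 104 without the HSC-3 0 Gy library replicate 2, and were 32 with lists of equal length.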

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

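Tests in this part were chosen after the pattern they address was seen, except the count of line-only regions over splits, which was planned before any peak was read but whose bound was written after the count was seen. The lengths of the longest runs with equal lists were also among the alternatives set before the data were examined. For the counts over splits of chromosomes and runs, for the check that takes the summit pileup off the local background and for the order of regions with equal lists, the bound was written before the value was computed.

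Of 36 sets of 4 library values tested for a value far from the rest, 2 had one, where chance gives about 1 in 20. Both were in the KOSC-2 0 Gy library replicate 1, which had 5.96% of its peaks on chromosome 5 against 5.20 to 5.27% in the other KOSC-2 libraries, and 5.54% on chromosome 7 against 5.29 to 5.31%. This library also had the highest background (64.8 reads per 10 kb) and an enrichment of 25.7.

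In KOSC-2, gained regions outnumbered lost regions (2828 against 701). Unequal list length was tested as an explanation: with the 4 lists cut to the same 38234 peaks the ratio fell from 4.03 to 1.77, between the bounds set for and against it. With equal lists the splits that mix doses gave ratios of 1.39 and 2.202, so 1.77 lies within what these 4 libraries give without regard to dose. Over the 6 splits of both lines, the side with more peaks had more regions of its own in 5. With equal lists the side holding the KOSC-2 0 Gy library replicate 1 had fewer regions of its own in every split, whatever the dose. In the splits that mix doses it had 1207 against 1676 and 669 against 1473. List length may thus account for part of the excess, and what remains went with this library. A response to irradiation of this size cannot be told apart from either with 2 libraries per dose.

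Chromosome shares differed between the lines. Chance is argued against as the source, since 13 chromosomes separated the lines and the highest other split separated 1. It is not excluded, because 1 of 35 splits is the smallest share possible and the shares of a library depend on each other. Unequal list length is argued against by the 11 chromosomes that still separated the lines with all lists cut to equal length, against at most 3 in other splits. Unequal DNA copy number of the lines is a candidate explanation: across 23 chromosomes, which are not independent replicates, the difference in local background (HSC-3 minus KOSC-2, log2) went with the log2 ratio of peak shares (Pearson r = 0.787, permutation p = 4e-05; Spearman rho = 0.727, permutation p = 0.00024). Chromosomes 19 and 22, 2 of the 13, went the other way, with local background 0.164 and 0.131 higher in HSC-3 (exact permutation p = 0.286 and 0.371) and log2 share ratios of -0.231 and -0.200. Bins of 10 Mb, however, differed in both directions, from -0.47 to 0.64 on chromosome 19 and from -0.39 to 0.71 on chromosome 22. Single libraries of low enrichment also stood apart on these chromosomes. The HSC-3 8 Gy library replicate 1 stood at 0.61 and 0.60 on chromosomes 19 and 22, against 0.06 to 0.34 in the other HSC-3 libraries. The KOSC-2 0 Gy library replicate 1 stood at 0.35 and 0.33, against 0.03 to 0.19 in the other KOSC-2 libraries. The value of the whole chromosome thus does not decide on copy number there. For local background itself 0 of 23 chromosomes passed adjustment (smallest adjusted p 0.0657), and 10 had an unadjusted p of 0.0286. Without chromosomes 5 and 18 r was 0.662. The reads of the peaks themselves as the source of this correlation cannot be told apart from copy number: with the summit pileup taken off the local reads r was 0.750, but regions called in all 8 libraries had a median width of 952 bp against fragments of 300 bp, so other peak reads stayed in. Differences in regulation along whole chromosomes stay open and were not tested.

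KOSC-2-only regions stood in long runs. Splits of the libraries do not decide on chance here (12 regions against at most 3 in the other 34 splits, 1 of 35 splits), because the real split also has the most one-sided regions. A chance order of the regions along the chromosomes is argued against with lists of equal length, where the longest KOSC-2-only run held 5, on chromosome 6, against a permuted median of 3 and maximum of 6 (permutation p = 0.00799). Clustering was not particular to KOSC-2 there, since the longest HSC-3-only run held 6 against a permuted median of 2 and maximum of 5 (permutation p = 0.000999). The 3 KOSC-2-only runs named above were not the longest with equal lists. Calls missed in the 2 short HSC-3 lists were tested at the 242 regions with 1 to 3 KOSC-2 calls inside the 18 runs of 5 or more. The 2 long lists had 5.38% of the calls expected there, so the absence was not confined to the short lists. Runs were, however, defined by 0 calls in all 4 HSC-3 lists, and a region called in all 4 would break a run. A low share is thus partly built in, and the test does not decide. Extra DNA copies in KOSC-2 did not show in the runs as a set, whose local KOSC-2 background differed by -0.0949 ± 0.253 (log2, SD, n = 4 libraries) from that of other KOSC-2-only regions. Single runs ranged from -0.71 to 0.63. The background of a list has its genome-wide level as lowest value, so a gain in DNA near that level would not show. The value of the set thus does not decide, and at the longest run the difference of 0.63 ± 0.40 was too variable to decide. DNA missing from HSC-3 may explain the 3 longest runs. There, 84 regions with 1 to 3 KOSC-2 calls had 0 HSC-3 calls against 73.7 expected, a gap that the choice of runs also widens in part. Missing DNA does not explain all 18 runs: 10, these 3 among them, held 0 HSC-3 calls, and the others held 21. A closed domain in HSC-3 predicts the same absence and stays open.

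The 1913 line-only regions were reached by 1 of the 35 splits, the real one, with 861 in the highest other split. This is the smallest share the splits allow, so chance is argued against for their total but not excluded.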

How the results depend on the processing

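Of 187 alternative values, 120 kept their direction and side of the threshold or stayed within 1.5 times the main count, 58 counts moved by more, 5 tests lost their call and 4 values reversed. A −log10 q of at least 5 and a 50% cover rule moved no count by over 1.5 times. Tests left out above for want of hg19 genes or sequence were not run. Alternatives without the 3 libraries of lowest enrichment, with equal lists within a line, with crossed pairs and with libraries left out for chromosomes and runs were chosen after seeing the data. The cause was not tested except where stated.

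Equal list length gave 717 KOSC-2-only, 507 HSC-3-only and 1224 line-only regions, 906 gained in KOSC-2, 32 lost in both lines, and longest runs of 5 (KOSC-2) and 6 (HSC-3). Equal lists within the line gave 1786 gained in KOSC-2. The upper 50% of each list kept fewer regions by construction: 216 KOSC-2-only, 43 HSC-3-only, 54 gained and 17 lost in KOSC-2, 17 gained and 44 lost in HSC-3. Calls in at least 3 of 4 libraries gave 5014 and 897 line-only regions and runs of 23 and 8. Without the 3 libraries of lowest enrichment there were 4526, 3169 and 7695 KOSC-2-only, HSC-3-only and line-only regions, runs of 21 and 11, and an overlap difference by line of 0.117 (exact p = 0.1, the smallest 3 against 2 allows). As a share of the shorter list, the overlap difference by dose turned to 0.0472 (exact p = 0.111, the smallest possible). With equal list length it was -0.00739 as a Jaccard index (exact p = 0.556).

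Leaving out 1 library gave 1731 to 4254 KOSC-2-only, 252 to 602 HSC-3-only and 2147 to 4664 line-only regions; 3850 to 11020 gained and 1106 to 6561 lost in KOSC-2; 760 to 9024 gained and 926 to 8510 lost in HSC-3. Shared by the lines were 34 to 360 gained and 14 to 104 lost. The overlap difference was 0.0554 to 0.128 by line and -0.0508 to 0.0221 by dose, the dose difference in peaks -2503 to 7789 (reversed, at -1966 and -2503, without the HSC-3 replicate 2 of 0 and of 8 Gy), and longest runs 12 to 21 (KOSC-2) and 3 to 7 (HSC-3). Fewer libraries to agree raises such counts by construction. Chromosomes without overlap numbered 11 to 17 over all alternatives, with 0 passing adjustment. The 17 came without the 3 libraries of lowest enrichment. With 3 against 2 libraries, chance separates chromosomes more often and no exact p can fall below 0.1.

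With the replicate number as a block, the peak differences of 11699 by line and 2643 by dose had exact p of 0.5 and 0.875 (smallest possible 0.125). Neither was a call without the block and neither could become one with it, so the block decides nothing here. It was fitted to peak numbers only. Deviations of libraries with the same number correlated at 0.018 in KOSC-2 and -0.154 in HSC-3, so the numbers were not taken to pair libraries. With the pairs crossed in HSC-3 the dose difference had an exact p of 0.75, with the same limit, and gained and lost regions cannot change with the pairing, as they need both libraries of a dose.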

Other observations

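The tests in this part were chosen after the values were seen. Local background under regions called in all 8 libraries differed between the lines over broad parts of some chromosomes. On chromosome 11, HSC-3 exceeded KOSC-2 in all 5 bins of 10 Mb from 1 to 50000000, by 0.40, 0.35, 0.72, 0.34 and 0.39 (log2) in order, and fell below it in each of the next 6 bins, by 0.87, 0.29, 0.86, 0.93, 0.79 and 0.42 in order from 50000001 to 110000000. The bin of 0.29, from 60000001 to 70000000, holds the most such regions of the chromosome (116) and did not separate the lines (exact permutation p = 0.114), so the difference is not an even step. From 110000001 to 120000000 the lines differed by 0.02. Within KOSC-2 the background from 70000001 to 80000000 stood 0.87 ± 0.10 (SD, n = 4) above the libraries' own medians, and in HSC-3 0.00 ± 0.07. Both chromosome 11 runs of KOSC-2-only regions lie between 50000001 and 110000000. On chromosome 5, HSC-3 exceeded KOSC-2 by 1.01 between 100000001 and 110000000 and by 1.15 between 160000001 and 170000000, the latter over 21 regions and with a wide spread in KOSC-2 (-0.66 ± 0.48 against 0.49 ± 0.05 in HSC-3, SD, n = 4 each). The KOSC-2 0 Gy library replicate 1 stood apart in its share of peaks on this chromosome. On chromosome 8, HSC-3 exceeded KOSC-2 by 0.93 between 70000001 and 80000000. Of 259 bins of 10 Mb with at least 20 such regions, 0 passed adjustment (smallest adjusted exact permutation p 0.0679), and 109 bins had an unadjusted p of 0.0286.

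The lists hold no measure of DNA copy number apart from the accessible regions themselves, so whole-genome or array data of both lines would be needed to say what these differences are. Over the whole of chromosome 11 local background differed by -0.02 (exact permutation p = 0.457), with bins in both directions.

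KOSC-2-only regions made up 12.4% of the regions called in 4 of 4 KOSC-2 libraries on chromosome 13, 11.4% on chromosome 19 and 10.7% on chromosome 18, against 3.32% on chromosome 10 and 3.96% on chromosome 17. On chromosome 19 the runs of 5 or more lay at 19976386 to 20607980, 21512022 to 22235479, 23945541 to 24270411, 37263545 to 37664003 and 37957691 to 38210978. They held 32, 37, 37, 33 and 27 KOSC-2 calls and 0, 1, 0, 0 and 0 HSC-3 calls. Over the whole of chromosome 19 local background was 0.16 higher in HSC-3 than in KOSC-2 (log2, exact permutation p = 0.286), with bins in both directions. HSC-3 was lower by 0.47 from 1 to 10000000 and by 0.34 from 10000001 to 20000000. It was higher by 0.16, 0.44 and 0.64 in the bins from 30000001 to 60000000. The HSC-3 8 Gy library replicate 1 stood at 0.61, against 0.08 to 0.23 in the other HSC-3 libraries. The value of the whole chromosome thus does not speak for the runs.

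Each of the 6 pairs of KOSC-2 libraries was set against the 2 long HSC-3 lists. The ratio of KOSC-2-only to HSC-3-only regions was 0.586 to 1.96 over these pairs, with a median of 1.08, against 6.90 with all libraries.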
